A study of Mus musculus with 9 samples.

How the data were processed

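RNA of 4 GSC lines, 3 gPS lines and 2 ESC arrays was measured on a mouse Illumina bead array. Per the labels, total RNA was amplified to biotin-labelled cRNA with the Illumina TotalPrep kit and hybridized to 1 array per sample. The deposited signal is an intensity per probe and array, summarised from beads and neither normalized between arrays nor background-subtracted. The submitters' processing notes name BeadStudio 3.2, RMA and lumi. Per the file headers, each signal has a detection p-value against the array's own negative controls. The authors' processed table holds log2 values with identical quantiles on all 9 arrays (median 2.99, maximum 14.5). Its log base is not stated and was taken as 2 from the maximum.

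The signal was background-corrected, quantile-normalized and log2-transformed with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and negative controls inferred from the detection p-values. Probes detected at p under 0.01 on at least 2 of the 9 arrays were kept (12695 of 25697). Gene symbols came from the platform table, where 23978 probes had 1 symbol and 1719 were not named in the tables used here. Each gene was represented by its probe with the highest mean, which gave 9488 genes, 738 of them unnamed. Kit, Zbtb16 and H19, which were to be reported, are not named in the tables used here. For genes with further probes, the probe used was ILMN_1252910 for Pou5f1, ILMN_2656102 for Sox2 and ILMN_2999439 for Klf4.

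A single limma model with a mean per group was fitted to all 9 arrays, and gPS was compared with GSC, ESC with GSC and gPS with ESC by its moderated test. An adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. Values are mean log2 ± SD, and changes are differences of means with their SE. Principal components and Pearson correlations were computed across genes. Numbers of detected probes were compared by exact two-sided permutation tests.

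Gene lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. The 28 lists were pluripotency transcription factors, embryonic stem cell associated genes, reprogramming factors, undifferentiated spermatogonia, germ cell identity, differentiating spermatogonia and meiosis, spermatids, Sertoli cells, Leydig cells, fibroblasts and feeder cells, endoderm, mesoderm, neural ectoderm, primed epiblast, trophoblast, two-cell-like genes, imprinted genes expressed from the paternal and from the maternal allele, DNA methylation machinery, Polycomb group, the LIF, BMP and Nodal response, glycolysis, oxidative phosphorylation, cell cycle, immediate-early and stress genes, cell adhesion and surface, sex chromosome genes and reference genes. They held 510 genes, of which 309 were tested, and some genes stand in more than 1 list. The 26 lists with at least 3 tested members were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. Camera compares a list with all other genes. Fry asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes.

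The genes named are, per comparison, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, with 1 symbol and without clone-type names. In addition, they are the 2 largest rises and the 2 largest falls of each list, or its 2 members with the highest mean where none passed, always Pou5f1, Nanog, Sox2, Klf4, Myc, Zfp42, Ddx4, Dazl, Zbtb16, Gfra1, Ret, Kit, Stra8, H19, Snrpn, Peg3 and Igf2r, and the 10 genes displaced furthest from ESC toward GSC. A gene named outside this rule is said to be chosen after its values were seen.

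The correlation of the changes in the comparisons with GSC was set against 50 simulations of unchanged groups, and the overlap was recomputed with the GSC arrays divided between the comparisons. The method was tested on 5 simulated sets per comparison, with 250 changed genes per size over the 5 sets together. Of changes of 1 on the log2 scale it recovered 66.8% for gPS against GSC, 54% for ESC against GSC and 44.8% for gPS against ESC, and of changes of 2 it recovered 99.6%, 98% and 99.6%. Of its calls, 5.14%, 3.93% and 3.47% were false. Far fewer genes changed in these sets than were called against GSC in the data (56.3% for gPS and 54.5% for ESC). The adjusted threshold was therefore stricter in the sets, and these values do not give the recovery in the real comparisons with GSC. A list shifted by 1 passed camera in 5 of 5 simulated sets in each comparison.

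Alternatives covered the background correction (none, or normexp with an offset of 50), the authors' processed values, median scaling, the detection filter (none, or all 9 arrays), the probes of a gene (all kept, or averaged), fitting only the compared groups, an intensity trend, the line number as a block, the ESC arrays averaged, each array left out, a 2-fold minimum, and the list test. GSC 1 and GSC 3 averaged or left out together were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.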

Results

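RNA levels were measured on 9 mouse Illumina bead arrays with 25697 probes each. Germ stem cells (GSC), stem cells of the adult germline that the labels call unipotent, were measured as 4 lines with 1 array per line. Germ pluripotent stem cells (gPS) were measured as 3 clonal lines sorted by GFP fluorescence, again with 1 array per line. Embryonic stem cells (ESC), the pluripotent reference, were measured on 2 arrays that the labels call a duplicate. The ESC duplicate may be technical, in which case it holds no spread between ESC cultures. All comparisons share 1 estimate of the spread from the 9 arrays, so p-values against ESC rest mostly on the spread among GSC and gPS lines. A technical duplicate could also make this estimate too small for gPS against GSC. The number of arrays limits the precision of every value. The labels do not say which GSC line each gPS line came from.

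The median signal before normalization lay between 83.6 and 101 on the 9 arrays, and between 9871 and 11813 probes were detected at a detection p under 0.01. Detected probes made up 44.0% ± 1.55 of the array in GSC (SD, n = 4), 39.5% ± 1.71 in gPS (SD, n = 3) and 39.2% ± 0.688 in ESC (SD, n = 2). The gPS arrays detected fewer probes than the GSC arrays (exact two-sided permutation test, p = 0.0286, the smallest p that 35 splits allow). For ESC and GSC the same exact permutation test gave p = 0.0667, the smallest that 15 splits allow, and for gPS and ESC it gave p = 1, where the smallest possible was 0.1. The first principal component of the 9488 genes tested held 77.3% of the variance and separated GSC (-67.1 to -64.1) from gPS (46.9 to 52.0) and ESC (56.1 to 56.5). Across genes, which are not independent replicates, the correlation between gPS and ESC arrays averaged 0.963 (0.951 to 0.972), close to that among gPS lines (0.966, from 0.961 to 0.972). It averaged 0.816 between GSC and gPS, 0.804 between GSC and ESC and 0.972 among GSC lines, and it was 0.987 for the ESC pair. The arrays of GSC 1 and GSC 3 correlated at 0.995, and the SD of their difference (0.21) was smaller than that of the ESC duplicate (0.34). GSC 1 and GSC 3 may therefore not be independent lines, in which case n = 4 overstates the number of GSC lines. The estimate of the spread that all comparisons share may then be too small as well.

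**Figure D1:**
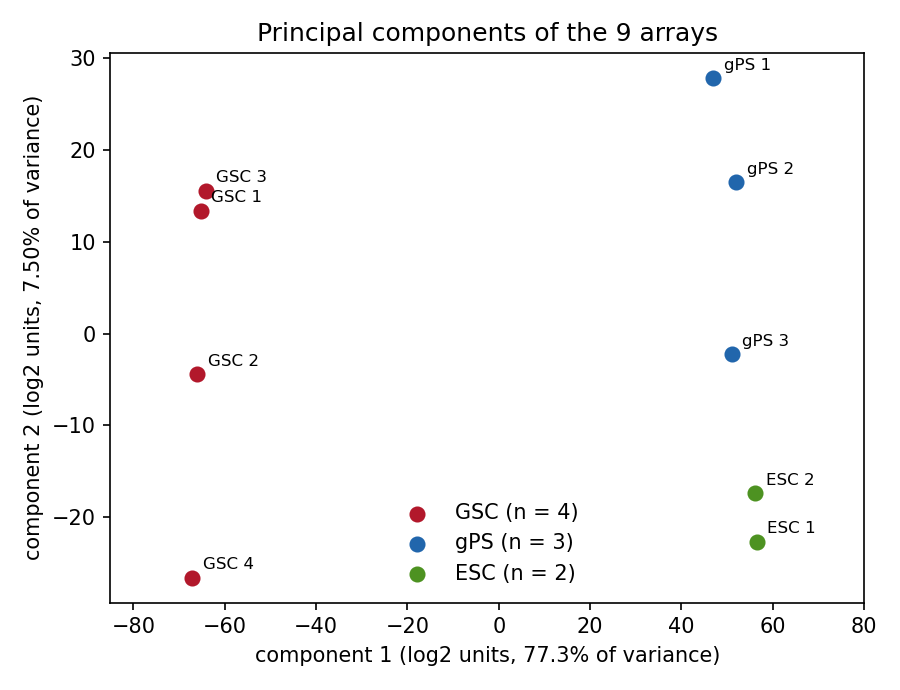
Scores of the 9 arrays on the first and second principal components of the normalized log2 values, with 1 point per array coloured by group (GSC, gPS, ESC). The first component (77.3% of the variance) places the 4 GSC arrays between -67.1 and -64.1 and the gPS and ESC arrays between 46.9 and 56.5, and the second (7.50%) places the ESC arrays at -22.7 and -17.4 and the gPS arrays between -2.26 and 27.8.

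The comparison of gPS with GSC asked what separates pluripotent lines derived from germline stem cells from the germline stem cells themselves. Nanog, a core pluripotency transcription factor, was detected on all 3 gPS arrays and on no GSC array, and was at least 46.9-fold higher in gPS (log2 10.40 ± 0.07 in gPS and 4.46 ± 0.07 in GSC, SD, n = 3 and n = 4). For a gene undetected on some or all arrays of the lower group, such a bound sets each of these undetected arrays to its lowest normalized value with a detection p under 0.01, or to the gene's own value if that is higher. Pou5f1 (Oct4), the other core factor, was already well detected in GSC (9.97 ± 0.90) and rose 5.76-fold, to 12.50 ± 0.18. Dazl, an RNA-binding protein that germ cells need, was not detected on any gPS array and was at least 148-fold lower there (adjusted p = 4.85e-10). Ret, the signalling receptor for the germline stem cell growth factor GDNF, was at least 17-fold lower in gPS, which detected it on no array.

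Of 15 measured pluripotency transcription factors, 13 rose, 1 fell and 1 did not pass (camera adjusted p = 2.22e-07, and adjusted p = 0.0412 with an estimated correlation). Adjusted over the list alone, 14 rose and 1 fell. Utf1, a chromatin-bound factor of pluripotent cells, rose at least 53.5-fold from a level detected on 3 GSC arrays, and Klf5 rose 51.4-fold. Stat3, the effector of LIF signalling, fell by 1.33 (SE 0.28), and Klf4, with a log2 change of 1.10 (SE 0.46, adjusted p = 0.0617), did not pass. Klf4 had 2 further probes with changes of 1.98 and 2.01, and it passed when the probes were averaged (adjusted p = 0.0202) and without gPS 2 (adjusted p = 0.00215). Among 24 genes associated with embryonic stem cells, 19 rose, 1 fell and 4 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 1.03e-09, and adjusted p = 0.0383 with an estimated correlation). Among those that rose were Lefty1, a secreted Nodal inhibitor (at least 105-fold, detected on 1 GSC array), and Dnmt3l, a cofactor of the de novo DNA methyltransferases (at least 112-fold, detected on 3 GSC arrays). Tex19.1, which is also expressed in germ cells, fell by 2.43 (SE 0.56). L1td1, an RNA-binding protein of pluripotent cells, was at least 72.2-fold higher in gPS and Trh, the precursor of thyrotropin-releasing hormone, at least 92.4-fold, with detection on 0 and 3 GSC arrays.

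Of the 4 reprogramming factors, Pou5f1, Sox2 and Myc rose and Klf4 did not pass, and adjusted over the list alone all 4 rose (camera adjusted p = 0.0211, but adjusted p = 0.317 with an estimated correlation). Sox2 rose at least 5.71-fold by the probe used, while its second probe changed by 1.10 on the log2 scale, and its level differed among GSC arrays. By the probe used it was 6.88 on GSC 1, 6.95 on GSC 3, 5.65 on GSC 2 and 4.55 on GSC 4, where it was not detected. Pou5f1 was likewise higher on GSC 1 and GSC 3 (10.59 and 10.77) than on GSC 2 and GSC 4 (9.71 and 8.81), and so was the mean of the fibroblast list, with 7.85 on GSC 1, 7.68 on GSC 3, 6.22 on GSC 2 and 5.43 on GSC 4. Myc was at least 3.09-fold higher in gPS and was not detected in GSC. Zfp42 (Rex1) rose by 1.99 (SE 0.21) and was detected on all 9 arrays.

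**Figure D2:**
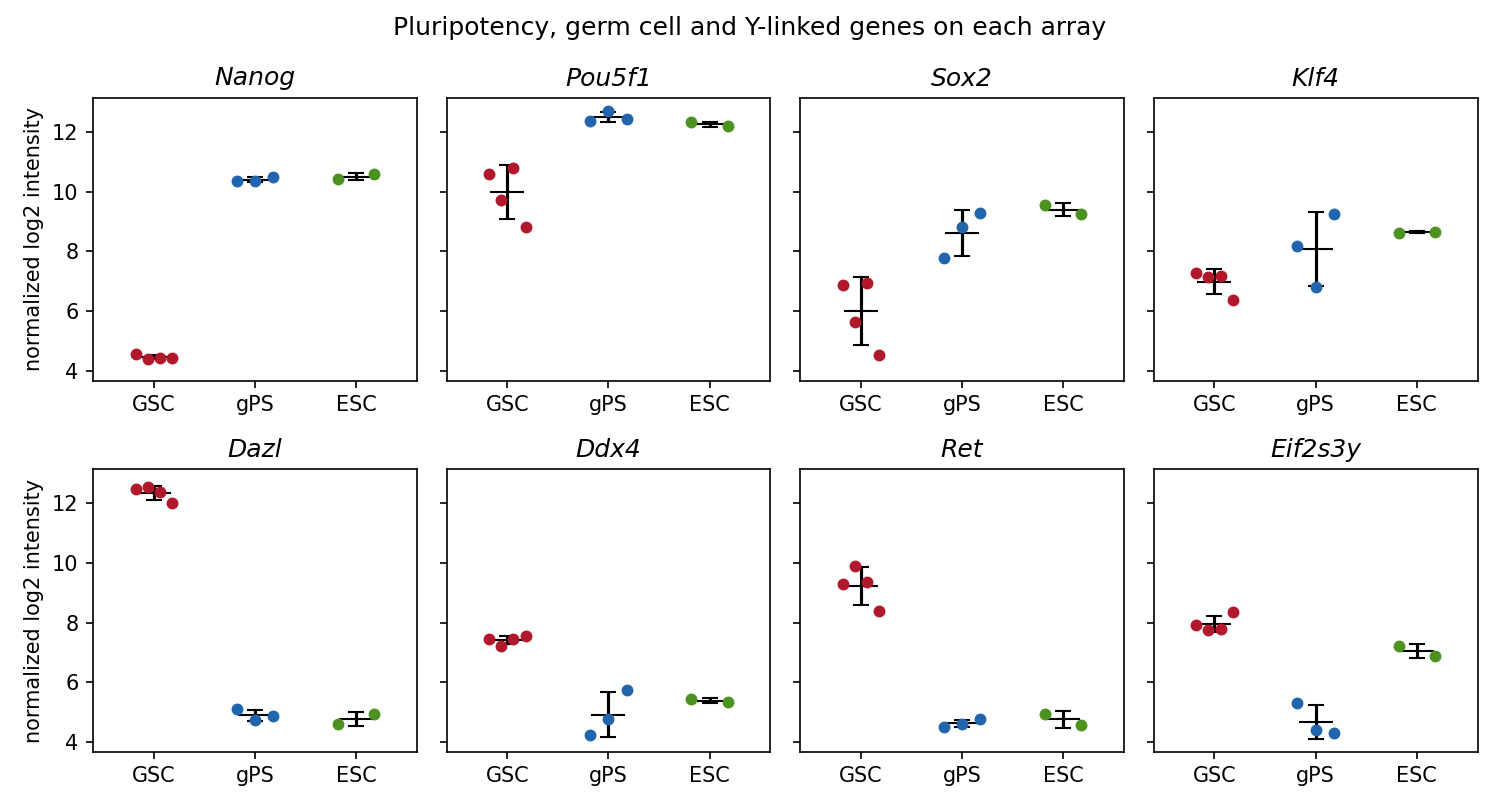
Normalized log2 values of 8 genes on each of the 9 arrays, with 1 point per array and the mean ± SD per group. Nanog stands at 10.40 ± 0.07 in gPS and 4.46 ± 0.07 in GSC, Dazl at 4.90 ± 0.19 and 12.35 ± 0.23, while Pou5f1 (9.97 ± 0.90) and Sox2 (6.01 ± 1.14) are already detected on GSC arrays.

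Germ cell genes fell almost as a block. Of 21 germ cell identity genes, 20 fell and D1Pas1 (log2 change -0.36) did not pass, while all 21 fell when adjusted over the list alone (camera adjusted p = 2.92e-13, and adjusted p = 0.00384 with an estimated correlation). Sohlh1, a transcription factor of spermatogonia, was at least 99.0-fold lower and Asz1, a component of the piRNA pathway, at least 52.6-fold lower, and neither was detected in gPS. Ddx4 (Vasa), a germ cell RNA helicase, was at least 4.10-fold lower and detected on 1 gPS array. Of 22 genes of undifferentiated spermatogonia, 14 fell, 3 rose and 5 did not pass, and adjusted over the list alone 15 fell and 3 rose (camera adjusted p = 0.0105, but adjusted p = 0.366 with an estimated correlation). The 3 that rose were Cdh1, the epithelial cadherin (at least 15.3-fold, detected on 1 GSC array), Etv5, a transcription factor (2.05, SE 0.42), and Itga6, an integrin chosen after its values were seen (at least 1.80-fold, detected on 3 GSC arrays). Egr4, detected on 1 gPS array, was at least 44.5-fold lower, while Gfra1, the GDNF co-receptor, was dim in GSC (5.09) and undetected in gPS, so that the size of its fall (adjusted p = 0.0157) has no bound, and it did not pass without gPS 2 (adjusted p = 0.0603) or without background correction (adjusted p = 0.0581). Of 17 genes of differentiating spermatogonia and meiosis, 12 fell and 5 did not pass, as also adjusted over the list alone (camera adjusted p = 0.000132, but adjusted p = 0.220 with an estimated correlation). Smc1b, a part of the meiotic cohesin, was at least 22.9-fold lower and undetected in gPS, and Stag3, another part, was at least 44.5-fold lower and detected on 2 gPS arrays. Stra8, the switch to meiosis, was detected on 3 GSC arrays, most strongly on GSC 4 (6.84), and on no gPS array, and did not pass (adjusted p = 0.0855), but it passed without GSC 4 (adjusted p = 0.0426), without GSC 2 (adjusted p = 0.0483) and with the authors' values (adjusted p = 0.0300). Of 5 spermatid genes, 1 rose, 3 fell and 1 did not pass (camera adjusted p = 0.709). Beyond these lists, Tuba3a, a testis tubulin detected on 2 gPS arrays, was at least 179-fold lower and Taf7l, a germ cell subunit of the general transcription machinery detected on 1 gPS array, at least 106-fold, and Hoxb7, a homeobox gene, was at least 42.0-fold lower.

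Of 18 LIF, BMP and Nodal response genes, 10 rose, 1 fell and 7 did not pass (camera adjusted p = 0.000132, but adjusted p = 0.0739 with an estimated correlation). Lefty2, a Nodal inhibitor like Lefty1, was at least 80.7-fold higher, and the member that fell was Stat3. Among 17 glycolysis genes 13 rose, 1 fell and 3 did not pass, and adjusted over the list alone 13 rose and 2 fell (camera adjusted p = 0.00053, but adjusted p = 0.366 with an estimated correlation). Pfkl, a phosphofructokinase subunit, rose by 3.17 (SE 0.40) and Tpi1, triosephosphate isomerase, by 3.02 (SE 0.40), but the second probe of Pfkl changed by 0.43 and the 2 further probes of Tpi1 by 0.89 and 3.19, and Aldoc, an aldolase, fell by 1.86 (SE 0.30). Of 19 cell cycle genes, 10 rose, 2 fell and 7 did not pass (camera adjusted p = 0.0218, but adjusted p = 0.220 with an estimated correlation). Ccne1, which drives entry into S phase, rose by 4.22 (SE 0.18) and Rrm2, which makes deoxynucleotides, by 3.16 (SE 0.20). Ccnd2, a D-type cyclin, fell by 3.06 (SE 0.33), and Cdkn2a, an inhibitor of the cell cycle, fell by 2.99 (SE 0.35). Of 16 cell adhesion and surface genes, 9 rose, 2 fell and 5 did not pass, and adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.0211, but adjusted p = 0.128 with an estimated correlation). The tight junction protein Cldn4, detected on 2 GSC arrays, rose at least 28.2-fold, and Ocln, another tight junction protein, was at least 1.96-fold lower and undetected in gPS. Oxidative phosphorylation genes went both ways, with 3 up, 4 down and 9 not passing among 16 (camera adjusted p = 0.803). Where counts adjusted over the list alone are not given for a list in this comparison, they equalled the counts over all genes.

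Markers of the early embryo and its derivatives rose in part. Of 10 primed epiblast genes, 6 rose, 1 fell and 3 did not pass, and adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.0133, but adjusted p = 0.128 with an estimated correlation). Nodal, a signal of the epiblast, was at least 16.4-fold higher and Cldn6, an epithelial claudin, at least 19.3-fold. Of 9 trophoblast genes, 5 rose and 4 did not pass (camera adjusted p = 0.102, though the list passed with median scaling and with GSC 1 and GSC 3 left out), with Bmp4 up at least 11.8-fold and the keratin Krt8 at least 9.06-fold, detected on 3 and 2 GSC arrays. The mean of the trophoblast list was 5.32 on GSC 1, 5.36 on GSC 3, 4.99 on GSC 2 and 4.83 on GSC 4. Of 10 endoderm genes, 3 rose, 1 fell and 6 did not pass, and adjusted over the list alone 3 rose and none fell (camera adjusted p = 0.202). Apoe, an apolipoprotein, rose by 3.36 (SE 0.48) and Lama1, a laminin chain detected on 3 GSC arrays, at least 5.14-fold, while the mean of the list was 6.59 on GSC 1, 6.53 on GSC 3, 5.79 on GSC 2 and 5.06 on GSC 4. Of 6 mesoderm genes, 1 rose, 2 fell and 3 did not pass (camera adjusted p = 0.764). Of 5 neural ectoderm genes, Gbx2, which is also a pluripotency-associated factor, rose by 5.66 (SE 0.27), Map2 rose, and 3 fell, among them Zic1, which was undetected in gPS and at least 10.3-fold lower. Zic1 differed among GSC arrays, with 9.64 on GSC 1, 9.65 on GSC 3, 8.28 on GSC 2 and 6.44 on GSC 4. The median of the neural ectoderm list was -0.91 and its mean -0.08, camera placed it down (adjusted p = 0.894) and fry up. Of 2 two-cell-like genes, Zscan4c, a gene of the cleavage-stage embryo, was at least 1.47-fold higher in gPS and undetected in GSC, and adjusted over the list alone both rose.

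Of 15 fibroblast and feeder cell genes, 2 rose, 3 fell and 10 did not pass (camera adjusted p = 0.894). Acta2, smooth muscle actin, rose by 3.25 (SE 0.58) and Tagln, an actin-binding protein undetected in GSC, by at least 1.28-fold, and Pdgfra, a growth factor receptor of mesenchymal cells, was at least 3.12-fold lower in gPS. Pdgfra stood at 7.44 on GSC 1, 7.52 on GSC 3, 6.60 on GSC 2 and 5.57 on GSC 4. Of 8 Sertoli cell genes, 5 rose, 2 fell and 1 did not pass, and adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.242, but fry up with an adjusted p = 0.00263). Among those that rose was Rhox5, an X-linked homeobox gene that is also active in embryonic stem cells (at least 6.62-fold), and Wt1, a transcription factor of the gonad detected on 2 gPS arrays, was at least 5.68-fold lower. The single Leydig cell gene tested, Fabp3, a fatty acid carrier known best from muscle, rose by 3.14 (SE 0.27).

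Of 14 genes expressed from the paternal allele, 6 rose, 5 fell and 3 did not pass, and adjusted over the list alone 7 rose and 6 fell (camera adjusted p = 0.352). Snrpn rose 17.2-fold (log2 change 4.10, SE 0.19), Impact by 2.96 (SE 0.20) and Peg3, detected on 3 GSC arrays, at least 3.24-fold. Dlk1, a growth regulator, fell by 2.25 (SE 0.56) but its groups overlapped, and on the GSC arrays Dlk1 stood at 9.81 (GSC 1), 9.75 (GSC 3), 8.53 (GSC 2) and 7.10 (GSC 4), in the order of the fibroblast list. Of 13 genes expressed from the maternal allele, 3 rose, 2 fell and 8 did not pass (camera adjusted p = 0.868, up), with a median of 0.05, a mean of -0.11 and fry pointing down. Igf2r, one of them, did not pass (-0.42, SE 0.26, adjusted p = 0.196), but it fell past the threshold without GSC 4 (-0.64, adjusted p = 0.0243), with averaged probes (-0.71, adjusted p = 0.0163), with median scaling (-0.93, adjusted p = 0.00734) and with the replicate block (-0.64, adjusted p = 0.0398), and its second probe fell further. The medians of both imprinted lists were above 0 and turned below 0 with median scaling in place of quantile normalization. Among 8 genes of the DNA methylation machinery 5 rose, 2 fell and 1 did not pass (camera adjusted p = 0.0837, though the list passed with median scaling and without a detection filter). Mbd3, a subunit of the NuRD complex, rose by 2.01 (SE 0.16), and the maintenance methyltransferase Dnmt1 fell by 0.60 (SE 0.17). Of 16 Polycomb genes, 7 rose, 5 fell and 4 did not pass (camera adjusted p = 0.738), and Cbx7 rose by 2.00 (SE 0.21) while its paralog Cbx8 was at least 5.59-fold lower. The Polycomb median of 0.12 also fell under 0 with median scaling, and its camera direction was up while that of fry was down. Of 7 sex chromosome genes, 3 rose, 2 fell and 2 did not pass, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.618), with a median that turned below 0 with median scaling. Both that fell are Y-linked, Eif2s3y (at least 6.82-fold lower, detected on 1 gPS array) and Kdm5d (at least 1.16-fold lower, detected on no gPS array), whereas the X-linked Eif2s3x rose by 2.74 (SE 0.27).

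Of 12 immediate-early and stress genes, 3 rose, 3 fell and 6 did not pass (camera adjusted p = 0.764, up), with a median of 0.24 that turned below 0 with median scaling, a mean of 0.08 and fry pointing down. Hspa1a, an inducible heat shock protein detected on 1 gPS array, was at least 3.71-fold lower. Of 11 reference genes often used as constant controls, 5 rose, 2 fell and 4 did not pass (camera adjusted p = 0.182). Rpl13a rose by 1.66 (SE 0.16), Gapdh by 1.48 (SE 0.16), and Tbp fell by 0.89 (SE 0.16).

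In total, 5346 of 9488 genes differed between gPS and GSC at an adjusted p under 0.05 (limma), 2426 higher and 2920 lower in gPS. A change of at least 2-fold was found for 2863 of them. The arrays of the groups did not overlap for 5286 genes (55.7%), where chance gives 5.71% if all arrays are independent, and more if GSC 1 and GSC 3 are not. The median log2 change of all genes was -0.07, and it was -0.39 with median scaling, where 27.5% of the called genes were higher in gPS in place of 45.4%. Of 26 lists tested, 11 passed camera (8 up, 3 down), and 3 of these held with an estimated correlation, while fry called 20, the same 11 and 9 that camera did not (up for the Sertoli, trophoblast, neural ectoderm, paternally expressed imprinted, DNA methylation, sex chromosome and reference lists, and down for spermatids and mesoderm).

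The comparison of ESC with GSC gives the distance between the germline stem cells and a pluripotent reference from the embryo. Nanog was at least 50.2-fold higher in ESC (10.50 ± 0.11, SD, n = 2) than in GSC (4.46 ± 0.07, SD, n = 4). Dnmt3l rose at least 145-fold and Ckb, a creatine kinase, 66.6-fold. Bcat1, a branched-chain amino acid transaminase detected on 1 GSC array, rose at least 84.2-fold by the probe used, but its 2 further probes changed by 2.43 and 2.68 on the log2 scale. Dazl was at least 146-fold lower, Sohlh1 at least 97.9-fold and Mageb4, a germ cell member of the MAGE family, at least 138-fold, and none of the 3 was detected in ESC by the probe used, while the second probe of Mageb4 fell by 3.68 on the log2 scale. Pou5f1 rose by 2.28 (SE 0.45, adjusted p = 0.00143) and Sox2 at least 9.75-fold (adjusted p = 0.000927, with a change of 1.37 by its second probe), while the mean of the fibroblast list on the GSC arrays ranged from 5.43 on GSC 4 to 7.85 on GSC 1.

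The lists that passed in gPS passed here with the same direction, apart from the primed epiblast list. Of 15 pluripotency transcription factors, 14 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.97e-08, and adjusted p = 0.0341 with an estimated correlation). Klf4 rose by 1.66 (SE 0.52, adjusted p = 0.0193, with 2.26 and 2.57 by its 2 further probes). It no longer passed with median scaling (1.13, adjusted p = 0.0796), without a detection filter (adjusted p = 0.0732), without ESC 1 or without ESC 2. Of 24 genes associated with embryonic stem cells, 20 rose and 4 did not pass, and 21 rose adjusted over the list alone (camera adjusted p = 1.23e-10, and adjusted p = 0.0303 with an estimated correlation). Germ cell identity genes fell in 20 of 21 cases, and D1Pas1 rose (camera adjusted p = 1.41e-11, and adjusted p = 0.00562 with an estimated correlation). With median scaling D1Pas1 did not pass (0.24, adjusted p = 0.268). The lists for undifferentiated spermatogonia (14 fell, 3 rose, adjusted p = 0.303 with an estimated correlation) and for meiosis (13 of 17 fell, adjusted p = 0.222 with an estimated correlation) passed camera only with the preset correlation. The same held for glycolysis (12 rose, 3 fell, and 13 rose and 3 fell adjusted over the list alone), cell cycle (10 rose, 2 fell), adhesion (10 rose, 1 fell), the LIF, BMP and Nodal response (11 rose, 1 fell) and the reprogramming factors (4 rose), for which the adjusted p with an estimated correlation was 0.463, 0.165, 0.0835, 0.0730 and 0.289. Trophoblast genes (5 of 9 rose, camera adjusted p = 0.0161) and the DNA methylation machinery (6 rose, 1 fell, camera adjusted p = 0.0165) passed as well, with an adjusted p = 0.240 and an adjusted p = 0.137 with an estimated correlation. Primed epiblast genes did not pass (4 rose, 2 fell, camera adjusted p = 0.119), and Otx2, which was at least 3.66-fold higher in gPS than in GSC, was undetected in both GSC and ESC. Rhox5 was at least 62.7-fold higher in ESC than in GSC, and Zscan4c at least 7.08-fold. Among the imprinted genes Phlda2 rose by 3.26 (SE 0.42), Grb10 by 2.10 (SE 0.44) and Snrpn by 3.50 (SE 0.21), and Igf2r did not pass (-0.76, SE 0.30, adjusted p = 0.0524), while under 7 alternatives it did, among them without GSC 4 (-0.98, adjusted p = 0.00558), without gPS 3 (adjusted p = 0.0394) and median scaling (-1.30, adjusted p = 0.00224). Grb10 differed among GSC arrays, with 8.13 on GSC 1, 8.07 on GSC 3, 6.76 on GSC 2 and 6.35 on GSC 4. The medians of both imprinted lists turned below 0 with median scaling. For mesoderm the median was 0.02 and the mean -0.10, and the median turned below 0 with median scaling and with the authors' values. For neural ectoderm both were below 0 while fry pointed up, and for oxidative phosphorylation both were below 0 (median -0.01, above 0 without background correction) while camera pointed up.

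In total, 5172 genes differed between ESC and GSC, 2358 higher and 2814 lower in ESC, and 3197 changed by at least 2-fold. The arrays did not overlap for 6549 genes (69.0%), where chance gives 13.3% if all arrays are independent, and more if the ESC arrays hold the same sample. The median log2 change of all genes was -0.11, and with median scaling it was -0.43 and 27.5% of the called genes were higher in ESC. Of 26 lists, 12 passed camera (9 up, 3 down), 3 of them with an estimated correlation, and fry called 17, the same 12 and 5 that camera did not (up for the Sertoli, primed epiblast, paternally expressed imprinted, sex chromosome and reference lists).

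Of the genes called in either comparison with GSC, 4295 were called in both with the same direction, 1912 higher and 2383 lower in pluripotent cells, and 2 with opposite directions. These were 80.3% of the gPS calls and 83.0% of the ESC calls, where independent lists would share 1469. Both comparisons use the GSC arrays. With separate GSC arrays for each comparison, 3314 to 3611 genes were shared. The log2 changes correlated at 0.934 across genes. The median was 0.382 in simulations of all arrays without group differences, where both comparisons also shared the simulated GSC arrays.

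**Figure D3:**
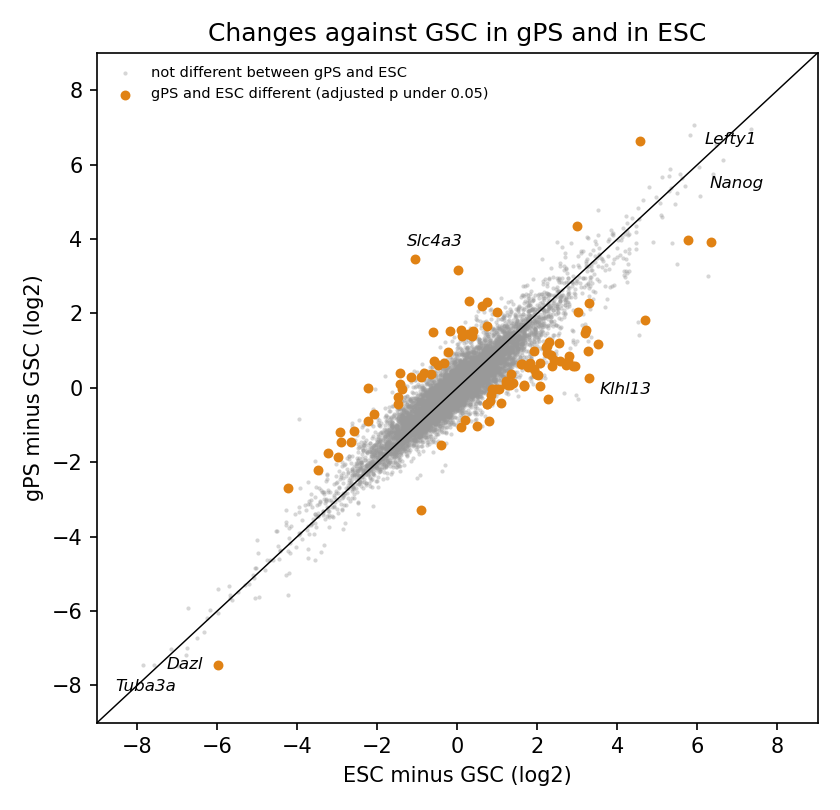
Log2 change of each of 9488 genes in ESC against GSC (x axis) and in gPS against GSC (y axis), with 1 point per gene and the 98 genes that differ between gPS and ESC in orange. The points follow the diagonal (Pearson r 0.934 across genes), with Lefty1 and Nanog at the upper end, Dazl and Tuba3a at the lower end, and Slc4a3 and Klhl13 away from it.

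The comparison of gPS with ESC asked how far the pluripotent lines of different origin differ. Nanog (-0.10, SE 0.17), Pou5f1 (0.25, SE 0.47) and Sox2 (-0.77, SE 0.65, and -0.27 by its second probe) all missed the threshold (adjusted p = 0.841, 0.862 and 0.631), which does not show that they were equal, since 44.8% of simulated changes of 1 were recovered in this comparison. Of the 15 pluripotency transcription factors 0 passed, and adjusted over the list alone 1 fell, Klf2, chosen after its values were seen (-0.97, SE 0.25), while the list had a camera p of 0.0376 (down, adjusted p = 0.196). Slc4a3, an anion exchanger, was 22.8-fold higher in gPS (SE 0.61 on the log2 scale, adjusted p = 0.00902), with 11.14, 10.13 and 8.40 in the 3 lines and 5.38 ± 0.03 in ESC (SD, n = 2), and its 2 further probes changed by 4.51 and 2.89. Nod1, a sensor of bacterial peptidoglycan, was 8.83-fold higher and L1td1 4.17-fold higher in gPS. Klhl13, a ubiquitin ligase adaptor, was at least 5.74-fold lower, Eif2s3y, a Y-linked translation initiation factor, at least 3.62-fold lower and Zscan4c at least 4.75-fold lower in gPS, where they were detected on 1, 1 and 2 arrays.

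Of the 26 lists, 0 passed camera, 5 had an unadjusted camera p under 0.05, 0 passed with an estimated correlation, and fry called 1, the sex chromosome list (down, adjusted p = 0.0233). The lowest camera adjusted p was 0.0900, for the primed epiblast list (up) and the sex chromosome list (down). Otx2, a transcription factor of the primed epiblast and forebrain, was the primed epiblast member that rose (at least 2.95-fold, adjusted p = 0.0260), and 3 rose adjusted over the list alone. The call of Otx2 was lost without background correction (adjusted p = 0.0809), with normexp (adjusted p = 0.0665) and with median scaling (adjusted p = 0.0710). In the sex chromosome list Eif2s3y fell (adjusted p = 0.00799), and 2 fell adjusted over the list alone. L1td1 was the embryonic stem cell associated gene that rose, with 3 up and 2 down adjusted over the list alone. Mcam, a surface glycoprotein of undifferentiated spermatogonia, rose by 1.53 (SE 0.24, with 0.86 and 1.10 by its 2 further probes), and was still lower than in GSC (-2.70). The integrin subunit Itgav was at least 1.71-fold lower and undetected in gPS, and Itga3, another one, fell by 1.85 (SE 0.35). D1Pas1 fell by 1.16 (SE 0.19) and Pcna, the sliding clamp of DNA replication, by 0.97 (SE 0.19). The calls of Itgav and Pcna were lost under every other scaling tried, for example median scaling (adjusted p = 0.116 and 0.105). That of Itga3 was lost with median scaling (adjusted p = 0.0650) and with the authors' values (adjusted p = 0.112). Those of Mcam and D1Pas1 were lost when only gPS and ESC arrays were fitted (adjusted p = 0.0624 and 0.110). In the other lists no member but Zscan4c passed over all genes, and at most 2 passed adjusted over the list alone. Rhox5 fell short of the threshold (-3.24, SE 0.79, adjusted p = 0.0845), with 9.67, 7.18 and 5.87 in the 3 gPS lines against 10.82 ± 0.25 in ESC (SD, n = 2), and passed without gPS 1 (adjusted p = 0.000694). The median, mean and camera direction differed in sign for the reprogramming factors, germ cell identity, meiosis, Sertoli, fibroblast and reference lists, whose medians all lay between -0.16 and 0.02, and fry pointed up and the rest down for the embryonic stem cell associated genes. The median turned its sign for meiosis and Polycomb with median scaling, for Sertoli and meiosis with the authors' values, and for meiosis without background correction.

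In total, 98 genes differed between gPS and ESC, 40 higher and 58 lower in gPS, 90 of them by at least 2-fold, and 1472 had an unadjusted p under 0.05. All 98 had arrays that did not overlap, as did 3094 genes of all tested (32.6%), where chance gives 20% if all arrays are independent. If the ESC arrays hold the same sample, chance gives a higher share, so this count is not shown to exceed chance. The share higher in gPS depended on the scaling, with 40.8% as reported, 30.5% without background correction, 31.0% with normexp and 60.8% with the authors' processed values. The count was 8 without ESC 1, 10 without ESC 2, 55, 58 and 51 without GSC 1, GSC 2 and GSC 3, 158 without gPS 1 and 159 without gPS 3, and it was 12 when only gPS and ESC arrays were fitted. Of the 24 named genes that passed, 5 (Klhl13, Pmel, Dlgap5, Apex1 and L1td1) passed under every alternative tried for them.

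To ask whether gPS lay between ESC and GSC, the 98 genes were compared with their change between ESC and GSC. In gPS, 72 were displaced from ESC toward GSC (20 higher and 52 lower than in ESC), 8 were displaced away from GSC, and 18 did not differ between ESC and GSC. The 52 were higher in ESC than in GSC, so they show a lower level than in ESC and not germline expression that remained. Of those named next, Klhl13 and Pmel were detected on no GSC array, Dlgap5 and Rgcc on 1 and Zp3 on 2. Among the 72 were Klhl13 (at least 5.74-fold lower), Pmel, a pigment cell protein that was not detected in gPS and at least 3.40-fold lower, Dlgap5, a mitotic spindle protein, which fell by 2.36 (SE 0.21), Rgcc, a cell cycle regulator, which fell by 2.33 (SE 0.23), Apex1, a DNA repair endonuclease, which fell by 1.93 (SE 0.19, and by 0.55 by its second probe), and Zp3, an egg coat glycoprotein detected on 1 gPS array and at least 3.51-fold lower. Gpn2, a GTPase, was 4.69-fold higher in gPS than in ESC. Among the 8 were L1td1 and Acot1, a thioesterase, both higher in gPS, and Eif2s3y, which was lower. The call of Eif2s3y between ESC and GSC was lost with the authors' values (adjusted p = 0.239) and without a detection filter (adjusted p = 0.0593). The ESC arrays serve both comparisons. With a different ESC array in each comparison, 7 of 8 and 9 of 10 called genes were displaced toward GSC. The count of 72 was 7 without ESC 1, 9 without ESC 2, 37, 42 and 33 without GSC 1, GSC 2 and GSC 3, 110 without gPS 1 and 109 without gPS 3.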

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

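The tests on fibroblast genes, on a share of pluripotent cells, on the displaced genes, on Eif2s3x and on Uty were chosen only after the result was seen.

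In the 4 GSC arrays, 14 of 162 values tested had an array whose gap to its nearest neighbour exceeded Dixon's critical value for 4 samples, where chance gives about 1 in 20, and GSC 4 was the outlying array for 10 of them. GSC 4 was lowest for Acta2 (log2 5.06, nearest 7.46), Asz1 (10.29, nearest 10.99), Gbx2 (5.09, nearest 5.54), Klf4 (6.37, nearest 7.15) and Tpi1 (8.27, nearest 9.70). It was highest for Smc1b (10.30, nearest 9.49), Snrpn (8.20, nearest 7.65), Stra8 (6.84, nearest 4.91), Tdg (6.57, nearest 6.28) and Tex11 (9.95, nearest 9.42). GSC 2 was lowest for Egr4 (10.51, nearest 11.41) and highest for Gapdh (13.025, nearest 12.64). GSC 1 was highest for Nanog (4.57, nearest 4.44) and Nodal (4.33, nearest 4.25), neither of which was detected on any GSC array.

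Genes of the fibroblast list were higher on GSC 1 and GSC 3 than on GSC 2 and GSC 4. On GSC 1, 93.3% of the 15 tested members were higher than on both (14, and 13 on GSC 3), against 30.5% of all genes, and its most abundant members in GSC, chosen after their values were seen, were Col5a1 (mean log2 9.18), Ccn2 (8.82), Sparc (8.51) and Dcn (8.03). RNA from feeder cells in the GSC cultures is a candidate explanation, but it cannot be told apart from expression by the germ cells themselves, because no independent measure of feeder cells was used here and members of the list were also high on the ESC arrays (Acta2 10.62), where feeder RNA was not tested either. The labels name a GFP sort for gPS and none for GSC, but whether it removed feeder cells was not tested. The mean of the fibroblast list on the gPS arrays was 6.85, 6.70 and 6.42, above GSC 2 (6.22) and GSC 4 (5.43). Acta2 was itself lower on GSC 1 (7.57) than on GSC 2 (7.95), unlike Ccn2, which was also high on the ESC arrays (10.79 and 10.35). Sox2 and Pou5f1 were also higher on GSC 1 and GSC 3. If a share of pluripotent cells on GSC 1 were the cause, Sox2 needs 14.6% and Pou5f1 24.7% of ESC RNA there. These shares and those that follow take GSC 4 as the baseline, the array flagged most often above, which did not detect Sox2. Another baseline would give other shares. The median over 26 genes at least 32-fold higher in ESC was 0.179%. These genes were chosen by their mean over the GSC arrays, GSC 1 included, so a low share was partly built in and the median cannot decide. Nanog, named by a rule fixed beforehand, gave 0.143%, far below both, but it is 1 gene.

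The 72 genes displaced from ESC toward GSC in gPS may reflect what the lines share by origin. GSC RNA in the gPS samples would need a median share of 87.9%, and the median over 27 genes at least 32-fold higher in GSC was 0.0213%, which argues against it. With a different ESC array in each comparison, 88.9% of the called genes (16 toward, 2 away) lay toward GSC, but the ESC arrays correlated at 0.987, more closely than any 2 gPS lines (at most 0.972), and may hold the same sample, so that a deviation of the ESC shared by both comparisons cannot be told apart from a difference of gPS. A genetic difference between the ESC line and the germline lines cannot be told apart from a remnant of the GSC state, because the labels used here give no strain. Of the 72 genes, 32 did not differ between gPS and GSC, 38 differed from GSC in the same direction as ESC and 2 in the other, at a median of 72.6% of the way from ESC to GSC. The 72 were chosen by a called displacement on these same arrays, so a large median was partly built in. It does not measure how far other genes of gPS lie toward GSC.

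Eif2s3y was lower in gPS than in ESC. Scaling was argued against, since under 4 other scalings the fitted log2 change lay between -4.04 and -1.11 and the highest adjusted p was 0.0462, with the authors' processed values. Signal from its X-linked counterpart on the probe was argued against too, because Eif2s3x differed by -0.13 (SE 0.33), far less than Eif2s3y. Loss of the Y chromosome in gPS lines could explain a part, but it cannot be told apart from lower expression, as the Y-linked Uty was detected on 1 gPS array and its change from ESC did not pass (adjusted p = 0.196). The call was lost when only gPS and ESC arrays were fitted (adjusted p = 0.0886), with the ESC arrays averaged (0.141), without ESC 1 (0.169) and without ESC 2 (0.0773).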

How the results depend on the processing

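GSC 1 and GSC 3 averaged or left out together were chosen after seeing the data, and the other alternatives before. No named gene changed direction past the threshold under any alternative tried for it, but medians near 0 of some lists changed sign with the scaling, as given with those lists. The share of genes called between gPS and ESC that were higher in gPS moved both ways. It went from 40.8% to 60.8% with the authors' values and to 30.5% without background correction, and the cause was not tested. Across the arrays left out in turn, the genes called numbered 4775 to 5331 for gPS against GSC, 3753 to 5399 for ESC against GSC and 3369 to 4365 in both, and the lists past camera stayed at 11, 12 and 0. With a 2-fold minimum these 3 counts of genes were 2863, 3197 and 2386. With genes detected on all arrays, fewer genes were tested and the counts were 3520, 3427 and 2835, with 5 lists past camera for gPS against GSC, 8 for ESC against GSC and 1 for gPS against ESC. Lists past camera with an estimated correlation were 3 in each comparison with GSC, and fry called 20 for gPS against GSC and 1 for gPS against ESC. The counts for gPS against ESC and for genes displaced toward GSC (98 and 72) were the least stable. They were 36 and 26 with median scaling, 37 and 28 with genes detected on all arrays, 12 and 10 with only the arrays of both groups, 8 and 7 with the ESC arrays averaged, 53 and 36 with GSC 1 and GSC 3 averaged and 33 and 19 with these left out. With the line number as a replicate block they were 20 and 15, beside 5049 genes for gPS against GSC, 4806 for ESC against GSC and 3982 in both, while the deviations of gPS and GSC arrays of the same number correlated at 0.08, -0.07 and -0.16 across genes, so the numbers were not read as pairs. They ranged from 8 and 7 (without ESC 1) to 159 (without gPS 3) and 110 (without gPS 1). Leaving out both GSC arrays or an ESC array lowers the number of samples. GSC arrays enter the test of gPS against ESC only through the shared estimate of the spread and the number of arrays behind it. Its count without GSC arrays therefore moved through that estimate alone, and it was 121 without GSC 4. The cause of the other changes was not tested. The mean correlation between gPS and ESC arrays (0.963) was 0.946 with the authors' values, 0.977 without a detection filter and 0.954 with genes detected on all arrays, and under these it was 0.766, 0.899 and 0.805 between GSC and gPS (0.816 as reported) and 0.751, 0.893 and 0.790 between GSC and ESC (0.804 as reported). Of the named genes called, 87 of 104 passed under every one of up to 22 alternatives for gPS against GSC, 86 of 100 for ESC against GSC and 5 of 24 for gPS against ESC. Some lists that did not pass camera as reported passed under an alternative. With GSC 1 and GSC 3 left out these were endoderm in both comparisons with GSC and trophoblast for gPS against GSC. With median scaling they were the reference genes in both, trophoblast and DNA methylation for gPS against GSC, and endoderm and primed epiblast for ESC against GSC. Without a detection filter it was DNA methylation for gPS against GSC, and with genes detected on all arrays they were the sex chromosome list in both and undifferentiated spermatogonia for gPS against ESC. Other lists were lost with genes detected on all arrays. For gPS against GSC these were adhesion, cell cycle, meiosis, the LIF, BMP and Nodal response, primed epiblast and undifferentiated spermatogonia. For ESC against GSC they were meiosis, DNA methylation and the LIF, BMP and Nodal response. The chip as a block was not run because the files name no chip. Where 1 array was left in a group, it was assumed to vary like the other groups. The median signal of detected probes was 2.10 to 3.16 times the background, so where arrays of the lower group did not detect a gene, its fold is given as a bound.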

Other observations

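The tests over splits of the arrays were planned, and the Y-linked genes and per-line values were chosen after their values were seen.

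Of the Y-linked genes, Usp9y, Kdm5d and Eif2s3y were lower in gPS than in GSC, and Uty did not pass (limma adjusted p = 0.519). On the ESC arrays Eif2s3y and Uty were detected, and Usp9y and Kdm5d were not. Usp9y, chosen after its values were seen, was clearly detected on all 4 GSC arrays (log2 8.11, 7.72, 7.94 and 8.50) and on no gPS or ESC array, and was at least 7.60-fold lower in gPS (adjusted p = 8.69e-08) and at least 7.51-fold lower in ESC (adjusted p = 3.35e-07). Kdm5d was detected on the GSC arrays only. Eif2s3y stood between 7.76 and 8.36 in GSC and at 7.20 and 6.87 in ESC, and at 5.32, 4.40 and 4.30 in the gPS lines, where gPS 1 alone detected it. Uty was dim in all groups, with means of 5.22 in GSC, 5.09 in gPS and 5.67 in ESC. In GSC it lay so near the detection limit that a fall in gPS could hardly show. The X-linked Kdm6a was higher in both pluripotent groups, by 1.76 in gPS and 1.73 in ESC.

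The gPS lines also differed among themselves. Their correlation with the mean of the ESC arrays across genes was 0.958 for gPS 1, 0.964 for gPS 2 and 0.975 for gPS 3. Rhox5 was nearest to its ESC level in gPS 1 (9.67) and furthest in gPS 3 (5.87), and Slc4a3 was furthest from its ESC level of 5.38 in gPS 1 (11.14) and nearest in gPS 3 (8.40).

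With the ESC arrays kept, the 7 GSC and gPS arrays were split into 4 and 3 in 35 ways. Only the real split gave as many called genes as the comparison of gPS with GSC (5346, against 193 for the highest other). This is the smallest share that 35 splits allow, and GSC 1 and GSC 3 may not be independent lines. Every other split also puts GSC and gPS arrays into the same group, which widens the spread within groups and lowers its count. The splits therefore do not exclude chance for this count. For the number of lists past camera, 5 of the 35 splits gave as many (11 for the real split, 13 for the highest other), so that chance is not excluded for it by this count. The 4 other splits left at least 5 of the 7 arrays parted as in the real split, but a further split that did so gave as few as 4 lists. Whether a kept part of the real contrast explains their counts was not tested.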
